A study of Mus musculus with 6 samples.

How the data were processed

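RNA of mouse blood mononuclear cells was measured in 6 samples, 3 from uninfected wild-type mice and 3 from mice infected with Candida albicans for 7 days. Per the labels' protocols, cells were isolated with Ficoll, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq kit. The authors deposited a single table of FPKM (fragments per kilobase of gene, scaled for library size) for 54532 genes, with 1 column per library, gene length, position and biotype. Builds GRCm38 and mm10, which are the same assembly, are named per the submitters' processing notes. The aligner, the counter, their settings and strand use are not given in the sources used here. Of the gene identifiers, 54409 are in GENCODE release M21, and 98.3% of these have the same coordinates there. No row lacked a gene, and 105 gene symbols were on more than 1 row.

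The deposited FPKM keep the depth. Each value multiplied by gene length was a whole multiple of a single step per library, within 0.01 read for 100% of the values above 0, so whole reads were counted. The recovered totals were 14635332, 14930799 and 15331560 reads in controls 1 to 3 and 15247950, 17474587 and 15002008 in infected 1 to 3. The library size that the FPKM imply was 0.841 to 0.885 times these totals in controls and 1.17 to 1.23 times in infected libraries. It equals each library's median-of-ratios size factor times the geometric mean of the totals, with a ratio of 1 in each library. The authors' FPKM are therefore scaled to the median gene and sum to different totals, 303192 to 607575 per library. The columns analysed here hold FPKM alone, so the count-based tests planned for raw counts were not run, and the test planned for FPKM was used.

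Values were analysed as log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 of 6 libraries, which left 10889 genes. Infected and control libraries were compared with limma 3.58.1 (eBayes with an intensity trend, two-sided, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Large changes also needed a log2 fold change of at least 1 in size. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over 38 lists, with an estimated correlation and fry as alternatives. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Shares of FPKM were compared by a two-sided exact permutation test with scipy 1.17.1 under Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, whose smallest p for 3 against 3 is 0.1. Similarity of libraries was described by Pearson and Spearman correlations, principal components and chi-square tests of the recovered reads.

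The tests, the 38 lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes in each direction among genes that passed, whose groups did not overlap and whose higher mean reached 5 FPKM, leaving out unnamed gene models and single immunoglobulin and T cell receptor segments. For each list it took up to 3 passing members with the largest change in the prevailing direction and 1 in the other direction, or the 2 highest members where none passed, and for sex Xist and 4 Y-linked genes. Other genes named in the text (S100a9, Ly6c2, Ccr2, Gata1, Epor, Car1, Gfi1, Cst7, Lat, Cd8b1, Ms4a1, Jchain, Hspa8, Gata6, Vsig4 and mt-Nd2) were chosen after their values were seen. A few genes that the rule took are not reported here. The lists cover neutrophils by granule stage, monocytes, dendritic cells, B, plasma, T, regulatory T and natural killer cells, platelets, erythroid cells, basophils and progenitors. The rest cover receptor segments, ribosomal and mitochondrial genes, interferon, antigen presentation, inflammation, fungal recognition, metabolism, protein folding, cell cycle, handling stress, complement and iron.

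The test was tried on simulated reads for the same genes in 5 runs of 200 changed genes each, with about 10869 genes tested per run. It recovered 23.3%, 82.7% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold, and 6.76% of its calls were false. Far fewer genes changed there than the 3517 called in the data, which makes the adjusted threshold stricter, and all genes of a group shared 1 dispersion. These rates are therefore not the detection limits of the data. A raised list was called in 5 of 5 runs and 0 of 100 lists without a change were called. Simulated genes were drawn independently, so these lists held no inter-gene correlation. In the data the estimated correlation reached 0.868, for mitochondrially encoded genes. The simulation therefore cannot show how often camera at the preset correlation calls correlated lists falsely. Alternatives were other pseudocounts (0.1 and 5), filters, scalings (median of ratios, TPM, quantile, removal of globin, immunoglobulin and mitochondrial genes), no trend, array weights, the replicate number as a block and each library left out. Added after the data were seen were limma's voom on recovered reads with either library size, protein-coding genes alone, and mitochondrially encoded mRNAs alone.

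The scaling to a median gene affects each statement of direction, since a gene counts as lower when it moves less than the median gene. How the authors counted reads shared with near-identical copies is not given in the sources used here. Gapdh, a glycolysis gene with many pseudogenes, reached 0.392 to 1.55 FPKM, while Pgk1 and Ldha lay between 66.0 and 101 FPKM. Values of globin, ribosomal protein, class I MHC and other paralogous genes are uncertain for that reason. Overlapping genes and antisense genes cannot be told apart where strand was not used.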

Results

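Mononuclear cells were isolated from mouse blood by Ficoll, a density step that leaves most granulocytes and red cells behind, and their total RNA was sequenced. The control group held 3 libraries from uninfected wild-type mice, labelled day 0, and the infected group held 3 libraries from wild-type mice 7 days into a systemic infection with Candida albicans, a yeast. The question was which blood-cell transcripts differ between infected and uninfected animals. The labels do not say that the 3 samples of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. Infection, collection day and any batch of collection coincide, so their effects cannot be separated by this design.

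Each library held between 14635332 and 17474587 reads assigned to genes, as recovered from the gene values, and 10506 to 10832 genes reached 1 FPKM. The 10 genes with most reads took 23.0% to 25.8% of the reads in control libraries and 13.3% to 16.0% in infected libraries. Libraries of one group resembled each other more than those of the other group. Pearson's r across genes was 0.979 to 0.982 among controls, 0.952 to 0.968 among infected libraries and 0.885 to 0.914 between groups, where genes are not independent replicates. The first principal component held 69.8% of the variance and the second 11.7%. No pair within a group agreed within sampling noise: chi-square per degree of freedom was 7.22 to 13.8 among controls and 59.3 to 99.6 among infected libraries. Xist, the transcript of the inactive X chromosome, ranged from 14.8 to 27.3 FPKM over the 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty did not exceed 0.0359 FPKM in any of them.

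The make-up of the RNA differed between the groups. Globin transcripts took 35.3% ± 1.94 (SD, n = 3) of summed FPKM in control libraries and 10.1% ± 1.65 (SD, n = 3) in infected libraries, and the 20 platelet genes took 5.001% ± 0.218 and 8.16% ± 1.01. Less globin raises each other share: of the FPKM outside globin, immunoglobulin and mitochondrial genes, the platelet share was 0.696 points higher in infected libraries. Immunoglobulin transcripts took 0.155% ± 0.00954 in control and 0.283% ± 0.0553 in infected libraries. As a share of recovered reads, immunoglobulin overlapped between the groups, at 0.0545% in infected 3 and 0.0543% to 0.0598% in controls. For each of the 3 shares of FPKM the groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 samples against 3 can reach (Benjamini-Hochberg adjusted 0.133 over 4 shares). Mitochondrially encoded transcripts took 10.1% ± 0.348 in control and 7.32% ± 6.01 in infected libraries, a difference inside the spread of the infected group (exact permutation p = 0.6). Most of that spread lay in mitochondrial rRNA, which took 10.2% in infected 1, 6.49% in infected 3 and 0.255% in infected 2, against 8.54% to 9.05% in controls. Without infected 2 the mitochondrial share was 0.118 percentage points higher in infected than in control libraries, the opposite sign to that over all libraries. Globin loci lie in near-identical pairs, so the split of reads between single globin genes is uncertain.

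**Figure D1:**
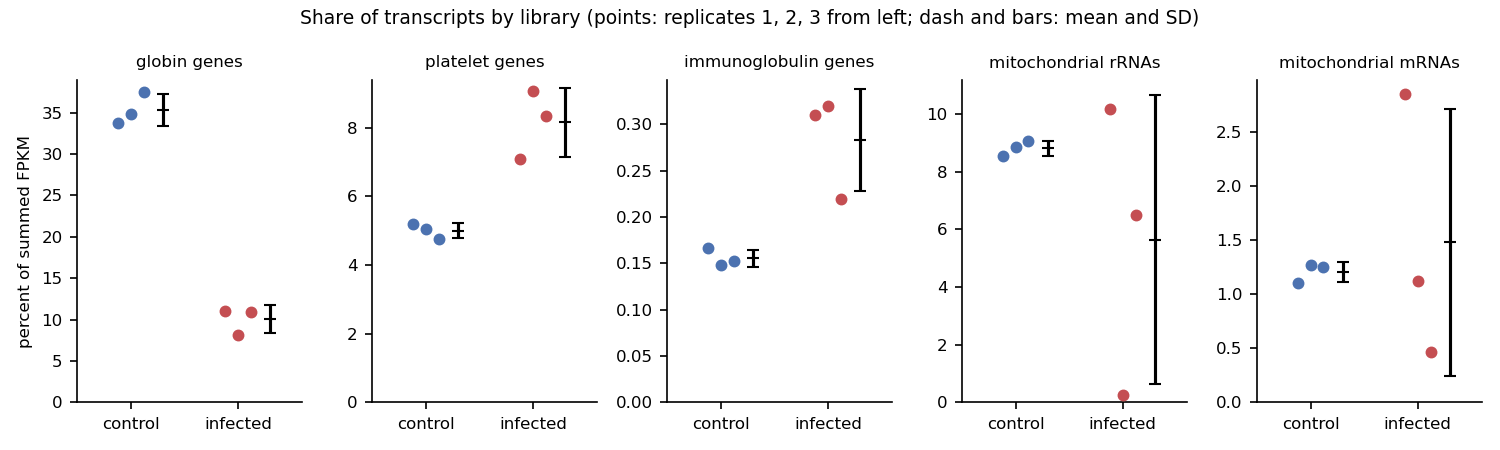
Each point is 1 library and gives the percent of summed FPKM on the vertical axis for globin, platelet and immunoglobulin genes, mitochondrial rRNAs and mitochondrial mRNAs; the dash and bars are the group mean and SD of 3 libraries. Globin falls from 35.3% to 10.1% of FPKM between the group means, and infected 2, the middle infected point, holds 0.255% mitochondrial rRNA.

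Infected libraries held high levels of transcripts that were scarce in controls. Saa3, an acute-phase serum amyloid gene, rose from 0.516 ± 0.114 to 116 ± 31.4 FPKM (mean ± SD, n = 3 per group, here and below). Alox15, a lipoxygenase, rose from 3.13 ± 0.471 to 300.1 ± 4.82 FPKM, and C4b, a gene of complement component C4, from 1.92 ± 0.613 to 149 ± 7.92. Transcripts of red-cell precursors and reticulocytes moved the other way. Slc4a1, the band 3 anion exchanger of the red-cell membrane, fell from 509 ± 12.3 to 33.9 ± 3.55 FPKM and Car2, a carbonic anhydrase, from 478 ± 11.3 to 39.1 ± 2.05.

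Of 10889 genes tested with limma on log2(FPKM + 1), 3517 had a Benjamini-Hochberg adjusted p under 0.05, with 1608 higher and 1909 lower in infected libraries. A change of at least 2-fold was seen for 1081 of them, 543 higher and 538 lower. The groups did not overlap for 5123 genes, or 47.0% of those tested, where chance gives 10%. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The deposited scaling puts the median gene at a log2 fold change of -0.01, whereas rescaling to TPM puts it at 0.66 and gives 7864 higher and 458 lower calls. Scaling recovered reads by library totals puts it at 0.46, with 5017 higher and 902 lower, and removing globin, immunoglobulin and mitochondrial genes puts it at 0.15, with 2640 higher and 1253 lower. Changes are therefore relative to the median gene, and without infected 2 the count was 2282, 863 higher and 1419 lower. Lower calls numbered 1222 without control 2 and 1261 without control 3. Of the 137 named genes, 7 turned direction on TPM, and of the 134 that passed 31 no longer did so there, 6 of those 7 among them.

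Besides Saa3, Alox15 and C4b, the 10 named genes with the largest rises were Prg4, the lubricating proteoglycan 4, Fn1, fibronectin, Lrg1, Cd14, the lipopolysaccharide co-receptor, Retnla, Cd5l, a secreted macrophage protein, and Il1r2, the interleukin-1 decoy receptor. Their log2 fold changes ran from 4.20 ± 0.16 (SE) for Il1r2 to 6.23 ± 0.20 for Saa3, with limma Benjamini-Hochberg adjusted p from 1.4e-06 for Alox15 to 5.0e-05 for Prg4. Fn1 rose from 9.91 ± 1.27 to 398 ± 119 FPKM, Retnla from 5.26 ± 0.533 to 147 ± 28.8 and Cd5l from 4.29 ± 0.782 to 96.9 ± 5.52. Among the 10 largest falls were those of Slc4a1, Apol11b, Car2, Rsad2, Trim10, Fech, Hbb-bt, Ctse and Cdr2. Their log2 fold changes lay between -3.88 ± 0.10 for Slc4a1 and -3.04 ± 0.11 for Cdr2, and limma adjusted p reached at most 6.6e-04, for Hbb-bt. Fech, the enzyme that completes haem, fell from 537 ± 23.7 to 58.7 ± 7.57 FPKM and Rsad2, the antiviral protein viperin, from 563 ± 3.73 to 49.1 ± 8.44. These genes stayed past the threshold with each library left out in turn, except that Saa3 and Il1r2 fell under the filter in the 3 fits that leave out an infected library. In GRCm38 coordinates Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46711998 to 46715700, and Alox15 (ENSMUSG00000018924) on chromosome 11 from 70344152 to 70352031. Slc4a1 (ENSMUSG00000006574) lies on chromosome 11 from 102348824 to 102366203, and Car2 (ENSMUSG00000027562) on chromosome 3 from 14886273 to 14900770. These are whole-gene spans.

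**Figure D2:**
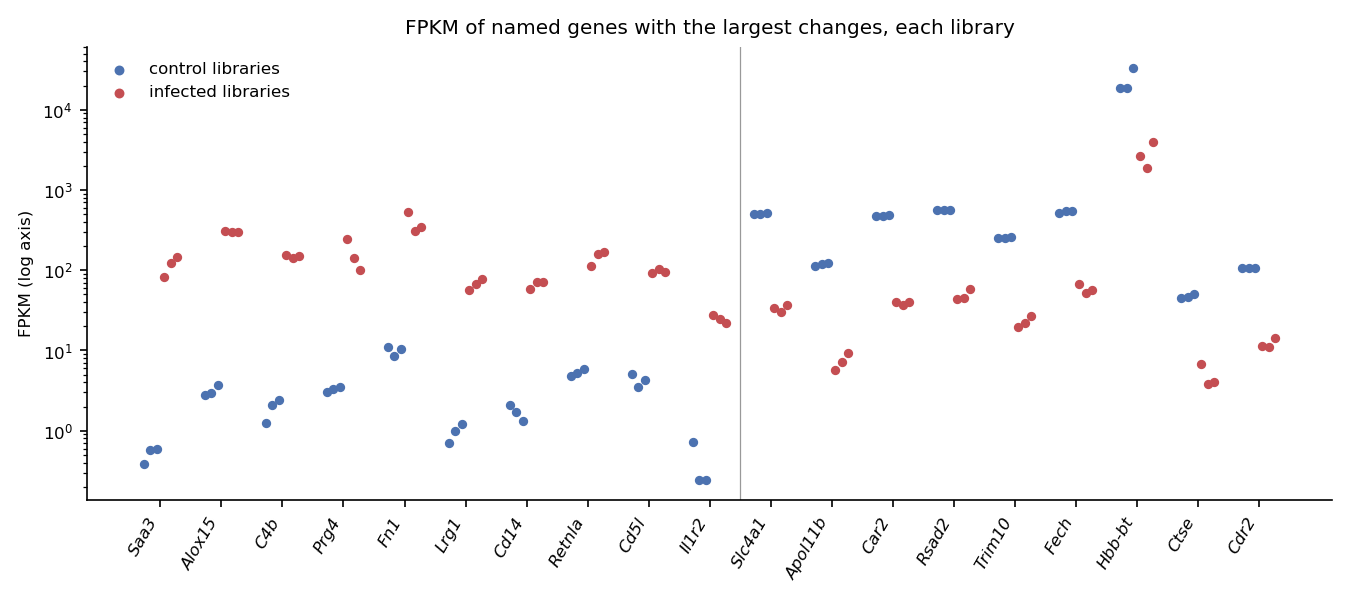
FPKM on a log axis of the named genes with the largest changes, 1 point per library, with 3 control and 3 infected libraries side by side. The groups are apart for each gene: Alox15 sits near 300.1 FPKM in the infected libraries and near 3.13 in controls, and Slc4a1 near 33.9 and 509.

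Genes of neutrophil granules rose as a group, although Ficoll leaves most neutrophils behind. All 15 measured secondary and tertiary granule genes rose (median log2 fold change 2.79, limma camera adjusted p = 6.3e-13, and 0.036 with an estimated correlation), as they did when adjusted over the list alone (15 genes). Chil3 rose from 31.6 ± 4.65 to 484 ± 82.6 FPKM, Mmp8, a collagenase, from 0.6604 ± 0.0642 to 22.1 ± 8.81, and Padi4, which citrullinates histones, from 0.865 ± 0.427 to 23.1 ± 2.49. Primary granule genes rose in 6 of 7 cases, also when adjusted over the list alone (median log2 fold change 1.70, limma camera adjusted p = 3.2e-05, adjusted p = 0.099 with an estimated correlation). Elane, neutrophil elastase, went from 21.6 ± 1.69 to 75.3 ± 7.61 FPKM and Prtn3, proteinase 3, from 9.76 ± 2.68 to 44.8 ± 4.88, while Gfi1 did not pass. Of 15 mature neutrophil markers 12 rose and none fell, with 13 higher and 0 lower when adjusted over the list alone (median log2 fold change 1.82, limma camera adjusted p = 2.6e-09, adjusted p = 0.080 with an estimated correlation). Among them were Retnlg, with 1.003 ± 0.402 FPKM in control and 34.9 ± 10.5 in infected libraries, and S100a9, with 110.1 ± 14.1 and 637 ± 138.

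Classical monocyte markers rose in 12 of 15 cases, the same number when adjusted over the list alone (median log2 fold change 1.90, limma camera adjusted p = 4.8e-10, and 0.036 with an estimated correlation). The largest rises were those of Fn1, Cd14 and Chil3, which macrophages or neutrophils can also express, while Ly6c2 and Ccr2 did not pass. Ly6c2, a usual sorting marker, had 18.2 ± 1.76 FPKM in control and 19.9 ± 6.34 in infected libraries and Ccr2 13.1 ± 1.12 and 15.6 ± 2.64. Complement genes rose in 12 of 14 cases, likewise when adjusted over the list alone (median log2 fold change 2.63, limma camera adjusted p = 2.8e-11, adjusted p = 0.080 with an estimated correlation). C1qc, a chain of C1q, rose from 3.51 ± 1.03 to 53.9 ± 4.79 FPKM and Cfp, properdin, from 9.97 ± 1.61 to 176 ± 22.9. MHC class II genes rose in 6 of 10 cases, also when adjusted over the list alone (median log2 fold change 0.69, limma camera adjusted p = 0.0037, adjusted p = 0.099 with an estimated correlation). H2-Eb1 rose from 113 ± 6.01 to 240.04 ± 60.7 FPKM and H2-Ab1 from 82.4 ± 1.58 to 145 ± 17.8. Among genes of tissue macrophages, Gata6 had 0.0324 ± 0.0213 FPKM in control and 2.84 ± 0.08803 in infected libraries, and Vsig4 had 0.0524 ± 0.0524 FPKM in control and 5.96 ± 1.37 in infected libraries. Nonclassical monocyte markers went both ways, with 3 higher, 4 lower and 5 of 12 not passing (4 higher and 4 lower when adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.562). Cd36, a scavenger receptor, fell from 46.5 ± 2.51 to 16.4 ± 2.75 FPKM and Cx3cr1 from 5.98 ± 0.182 to 2.95 ± 0.953, whereas Cd300ld rose from 3.21 ± 0.234 to 9.13 ± 2.25. Conventional dendritic cell markers gave 1 rise and 3 falls of 10 (3 higher and 3 lower when adjusted over the list alone, limma camera adjusted p = 0.594). Irf8 fell from 20.6 ± 2.45 to 10.4 ± 0.391 FPKM and Clec9a from 6.36 ± 1.299 to 2.73 ± 0.281. Of 12 plasmacytoid dendritic cell markers 2 fell (0 higher and 1 lower when adjusted over the list alone), led by Irf7 from 27.7 ± 1.14 to 7.799 ± 1.55 FPKM. That list was not called (limma camera adjusted p = 0.163), but was called with no filter, on TPM and without control 3 (limma camera adjusted p from 0.0159 to 0.445 over all alternatives).

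Erythroid transcripts fell almost throughout. Of 35 measured erythroid genes 32 fell and none rose, also when adjusted over the list alone (median log2 fold change -2.36, limma camera adjusted p = 6.0e-21, and 0.036 with an estimated correlation). Gata1, Epor and Car1 did not pass. Trim10 fell from 254 ± 7.44 to 22.8 ± 3.83 FPKM. Platelet and megakaryocyte genes went both ways: 3 rose, 7 fell and 9 of 19 did not pass, with 3 higher and 7 lower when adjusted over the list alone (limma camera adjusted p = 0.504). Gp6, the platelet collagen receptor, fell from 171 ± 0.296 to 94.7 ± 8.67 FPKM, Ppbp from 8232 ± 477 to 4260.1 ± 976, and Pf4 rose from 3271 ± 198 to 5864 ± 1465. The call of Pf4 was lost without control 1, control 2, control 3 or infected 2 (limma adjusted p up to 0.0827). Of 8 basophil, mast cell and eosinophil genes 2 rose and 2 fell (2 higher and 2 lower when adjusted over the list alone, limma camera adjusted p = 0.909). Hdc, histidine decarboxylase, rose from 0.719 ± 0.137 to 3.97 ± 0.112 FPKM and Il4 fell from 6.42 ± 1.397 to 1.42 ± 0.516. Progenitor genes gave 1 rise and 4 falls of 7 (1 higher and 4 lower when adjusted over the list alone, limma camera adjusted p = 0.246), with Adgrg1 at 166 ± 2.98 FPKM in control and 84.5 ± 20.1 in infected libraries.

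Transcripts of T cells and of natural killer and cytotoxic lymphocytes fell, in libraries whose neutrophil genes rose and whose globin share was lower. Of 23 natural killer and cytotoxic genes 22 fell and none rose, also when adjusted over the list alone (median log2 fold change -1.51, limma camera adjusted p = 8.6e-13, adjusted p = 0.115 with an estimated correlation). Ncr1, the receptor NKp46, fell from 34.5 ± 1.67 to 6.89 ± 2.47 FPKM, Prf1, perforin, from 40.1 ± 4.62 to 8.81 ± 1.69, and Cst7 did not pass. T cell markers fell in 21 of 23 cases (1 higher and 21 lower when adjusted over the list alone; median log2 fold change -0.85, limma camera adjusted p = 9.0e-08, adjusted p = 0.122 with an estimated correlation). Cd5 fell from 20.5 ± 1.89 to 6.599 ± 2.44 FPKM, Cd3e from 13.2 ± 1.02 to 5.17 ± 2.19 and Lck, a kinase of the T cell receptor, from 46.6 ± 3.102 to 20.2 ± 3.56, whereas Cd8b1 did not pass and Lat was higher only when adjusted over the list alone. Medians of both lists stayed negative under each scaling run. Over all settings the highest median was -0.78 for natural killer genes but -0.12 for T cell markers, so the size of the T cell fall depends on the setting. Of 20 T cell receptor variable segments 5 fell (0 higher and 4 lower when adjusted over the list alone; median log2 fold change -0.61, limma camera adjusted p = 0.0099, adjusted p = 0.104 with an estimated correlation). Trdv4, a delta-chain segment, fell from 9.37 ± 2.26 to 0.627 ± 0.452 FPKM, and the call of the list was lost with a minimum of 5 FPKM, without infected 1 and with voom (limma camera adjusted p from 8.3e-12 to 0.418 over all alternatives). Regulatory T cell markers gave 2 rises and 3 falls of 9 (2 higher and 3 lower when adjusted over the list alone, limma camera adjusted p = 0.556). Ctla4 rose from 5.11 ± 1.13 to 10.2 ± 1.73 FPKM and Ikzf2 fell from 2.33 ± 0.107 to 0.959 ± 0.15004.

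B cell markers were not called as a list (median log2 fold change -0.24, limma camera adjusted p = 0.255), and their median turned positive on TPM, at 0.54, and with library totals, at 0.22. Of 19 measured members 1 rose and 6 fell, with 1 higher and 8 lower when adjusted over the list alone. Vpreb3, a surrogate light chain gene, fell from 5.86 ± 2.17 to 0.477 ± 0.159 FPKM, while Ms4a1, CD20, had 7.72 ± 0.552 FPKM in control and 8.72 ± 1.397 in infected libraries and did not pass. Plasma cell markers gave 3 rises and 1 fall of 14 (3 higher and 1 lower when adjusted over the list alone, limma camera adjusted p = 0.542). Xbp1 rose from 10.9 ± 0.839 to 22.7 ± 1.2002 FPKM, and Jchain, with 5.16 ± 1.48 and 5.93 ± 0.879, did not pass. Of 54 immunoglobulin variable segments 4 rose, 0 when adjusted over the list alone with limma (11 at an unadjusted p under 0.05), and the list was not called (limma camera adjusted p = 0.635). Its median log2 fold change was -0.0082 and its mean 0.07, which differ in sign, and it was called on TPM and with voom and library totals (limma camera adjusted p from 3.2e-05 to 0.9999 over all alternatives), as lower than other genes. Ighv11-2 rose from 0.617 ± 0.6799 to 3.59 ± 1.597 FPKM, a call lost without control 2 (limma adjusted p = 0.0521).

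In the C-type lectin and fungal recognition list 19 of 28 genes rose and 1 fell (20 higher and 1 lower when adjusted over the list alone; median log2 fold change 0.82, limma camera adjusted p = 1.2e-07, adjusted p = 0.104 with an estimated correlation). Card9, the adaptor of fungal lectin signalling, rose from 2.56 ± 0.6902 to 15.7 ± 1.67 FPKM and Itgam, CD11b, from 3.81 ± 0.497 to 30.7 ± 0.531. The fall was that of Syk, a kinase, from 55.5 ± 2.18 to 45.8 ± 2.55 FPKM. Its log2 fold change was positive on TPM (0.51), and its call was lost without control 1, control 2, control 3 or infected 2 (limma adjusted p up to 0.152). Cytokine and chemokine genes gave 8 rises and 1 fall of 12, the same when adjusted over the list alone (median log2 fold change 1.38, limma camera adjusted p = 2.6e-04, adjusted p = 0.080 with an estimated correlation). The list names 29 genes, and those not among the 12 missed the filter, which a gene can pass through the infected libraries alone. With no filter the median was only 0.13, though the list was still called (limma camera adjusted p = 9.3e-04). Cxcl2, a neutrophil attractant, rose from 0.325 ± 0.04196 to 8.69 ± 1.01 FPKM and Ccl9 from 3.11 ± 0.489 to 27.7 ± 3.72, while Ccl4 fell from 8.57 ± 1.34 to 3.43 ± 1.004. Inflammasome and cell death genes rose in 11 of 16 cases (12 higher and 0 lower when adjusted over the list alone; median log2 fold change 0.76, limma camera adjusted p = 6.1e-06, adjusted p = 0.080 with an estimated correlation), Il1b from 1.11 ± 0.336 to 10.4 ± 0.251 FPKM and Nlrp3 from 0.701 ± 0.221 to 4.11 ± 0.594. The secondary and tertiary granule, mature neutrophil and classical monocyte lists rose in the same libraries, with medians of 2.79, 1.82 and 1.90. Whether more transcripts of such cells account for the fungal recognition, cytokine and inflammasome rises was not tested. Among immediate early and handling stress genes 14 of 24 rose and 1 fell (16 higher and 1 lower when adjusted over the list alone; median log2 fold change 1.07, limma camera adjusted p = 2.3e-07, and 0.036 with an estimated correlation). Dusp1, a phosphatase, rose from 16.2 ± 1.496 to 164 ± 8.79 FPKM and Fos from 12.4 ± 1.67 to 126 ± 10.4. Heat shock members did not rise: Hspa8 had 141 ± 2.74 FPKM in control and 135 ± 17.4 in infected libraries and did not pass. Hsph1 fell from 15.5 ± 0.545 to 9.48 ± 2.39 FPKM, which on TPM was a log2 fold change of 0.0555, and its call was lost without control 1, control 2, control 3 or infected 2 (limma adjusted p up to 0.0699).

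Interferon-induced genes fell on balance relative to the median gene, with list medians that turned positive on TPM. Of 32 type I interferon-stimulated genes 3 rose and 16 fell (5 higher and 19 lower when adjusted over the list alone; median log2 fold change -0.42, limma camera adjusted p = 9.9e-04, adjusted p = 0.080 with an estimated correlation), with a median of 0.34 on TPM, which is -0.32 relative to all genes there. Isg15 fell from 191 ± 11.6 to 29.6 ± 11.5 FPKM and Rsad2 as above, whereas Ifitm3 rose from 115 ± 5.89 to 299.96 ± 34.6. Isg20, which is also in the erythroid list, fell from 335 ± 8.48 to 83.7 ± 9.36 FPKM. The erythroid, natural killer and T cell lists fell in the same libraries, with medians of -2.36, -1.51 and -0.85. Whether fewer transcripts of such cells account for the interferon falls was not tested. Of 27 interferon-gamma-inducible GTPase and antigen presentation genes 2 rose and 11 fell, the same when adjusted over the list alone (median log2 fold change -0.30, limma camera adjusted p = 0.026, adjusted p = 0.191 with an estimated correlation), and the median turned positive on TPM, at 0.42, and with library totals, at 0.15. The call was lost with a minimum of 5 FPKM, on TPM, with quantile normalization, with globin, immunoglobulin and mitochondrial genes removed, without control 1, without control 2, without control 3 and with voom and library totals (limma camera adjusted p from 5.5e-04 to 0.495 over all alternatives). Tgtp2 fell from 4.96 ± 0.224 to 1.14 ± 0.408 FPKM and Gbp2b, a guanylate-binding protein, rose from 0.339 ± 0.137 to 7.29 ± 0.285. Type 17 genes gave 3 rises and 2 falls of 8 (3 higher and 3 lower when adjusted over the list alone, limma camera adjusted p = 0.848). Stat3 rose from 11.9 ± 0.391 to 15.8 ± 0.478 FPKM, a call lost without control 1 (limma adjusted p = 0.0538).

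The phagocyte oxidase and antioxidant list was not called (limma camera adjusted p = 0.140), but was called with no filter (limma camera adjusted p from 0.0388 to 0.435 over all alternatives). It held 7 rises and 3 falls of 15, the same when adjusted over the list alone. Cybb, the catalytic oxidase subunit, rose from 16.2 ± 2.96 to 61.6 ± 10.4 FPKM and Ncf1 from 9.997 ± 1.61 to 31.7 ± 1.899, while Gpx1 fell from 1740.5 ± 111 to 402 ± 24.7. Suppression and checkpoint genes gave 6 rises and 2 falls of 16, the same when adjusted over the list alone (limma camera adjusted p = 0.132). Wfdc17 rose from 2.86 ± 1.22 to 53.8 ± 12.1 FPKM and Socs3, an inhibitor of cytokine signalling, from 4.58 ± 1.102 to 42.6 ± 3.87. Iron and haem genes gave 8 rises and 3 falls of 16 (9 higher and 4 lower when adjusted over the list alone, limma camera adjusted p = 0.051) and the list was called with a pseudocount of 0.1, with no filter, with quantile normalization and without control 2 (limma camera adjusted p from 0.00603 to 0.232 over all alternatives). Hp, haptoglobin, rose from 8.17 ± 0.413 to 110.1 ± 21.9 FPKM and Blvrb, a biliverdin reductase, fell from 97.6 ± 6.89 to 30.98 ± 10.9.

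Unfolded protein response genes rose in 11 of 18 cases and fell in 3 (11 higher and 3 lower when adjusted over the list alone; median log2 fold change 0.52, limma camera adjusted p = 0.0099, adjusted p = 0.231 with an estimated correlation), a call lost on TPM (limma camera adjusted p from 0.00135 to 0.08198 over all alternatives). Hspa5, the chaperone BiP, rose from 34.8 ± 1.27 to 79.5 ± 16.5 FPKM. Oxidative phosphorylation genes gave 12 rises and 1 fall of 72 (10 higher and 1 lower when adjusted over the list alone; median log2 fold change 0.26, limma camera adjusted p = 0.0077, adjusted p = 0.557 with an estimated correlation). Fry of limma, which tests whether a list's genes move one way without comparing them with other genes, did not call that list (adjusted p = 0.097), whereas camera at the preset correlation did in each alternative run (adjusted p from 2.0e-04 to 0.0337). Cox4i1 rose from 61.9 ± 2.65 to 129 ± 32.4 FPKM. Cytosolic ribosomal protein genes gave 10 rises of 81, and 1 when adjusted over the list alone (median log2 fold change 0.15, limma camera adjusted p = 0.026, adjusted p = 0.678 with an estimated correlation). That call was lost without control 1, without control 2, without infected 2 and with protein-coding genes alone (limma camera adjusted p from 4.5e-08 to 0.133 over all alternatives), and limma's fry did not make it (adjusted p = 0.1795). Rps27a, with the largest rise, went from 20.6 ± 2.502 to 66.3 ± 4.59 FPKM. Reads of ribosomal protein genes are shared with pseudogenes, so single values are uncertain. Glycolysis genes went both ways, with 10 rises and 6 falls of 21 (12 higher and 7 lower when adjusted over the list alone, limma camera adjusted p = 0.094), and the list was called with no filter, on TPM, with quantile normalization and with voom and library totals (limma camera adjusted p from 0.002197 to 0.232 over all alternatives). Hk3, a hexokinase, rose from 2.701 ± 0.474 to 12.7 ± 3.54 FPKM and Pfkfb3 fell from 14.6 ± 1.05 to 8.04 ± 1.09. Cholesterol synthesis genes gave 5 rises and 1 fall of 14, the same when adjusted over the list alone (limma camera adjusted p = 0.183), with Mvd, a decarboxylase of the pathway, rising from 4.26 ± 0.836 to 8.45 ± 1.68 FPKM. None of the 12 mitochondrially encoded mRNAs passed with limma, and 1 did at an unadjusted p under 0.05, mt-Nd2. As a list they were not called (limma camera adjusted p = 0.094), but were called with no filter, on TPM, with array weights, without infected 1 and with voom and library totals (limma camera adjusted p from 6.6e-05 to 0.446 over all alternatives), as lower than other genes. mt-Co1 had 3122 ± 368 FPKM in control and 2779 ± 2349 in infected libraries.

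Cell cycle genes showed few changes. Of 23 S phase genes 1 rose and 2 fell (1 higher and 0 lower when adjusted over the list alone, limma camera adjusted p = 0.453). E2f1 rose from 2.23 ± 0.151 to 4.08 ± 0.347 FPKM. Mcm2 and Uhrf1 fell, but their log2 fold changes were positive on TPM (0.23 and 0.36). The call of Mcm2 was lost without control 2, control 3, infected 2 or infected 3 (limma adjusted p up to 0.0795), and that of Uhrf1 lost without control 1, control 3, infected 1, infected 2 or infected 3 (limma adjusted p up to 0.152). Of 28 G2 and mitosis genes 2 rose and 2 fell (1 higher and 2 lower when adjusted over the list alone, limma camera adjusted p = 0.453), with a median log2 fold change of 0.14 and a mean of -0.05. Ube2c, a ubiquitin-conjugating enzyme of mitosis, fell from 35.4 ± 3.61 to 4.73 ± 1.78 FPKM and Cdc20 rose from 4.38 ± 0.527 to 7.57 ± 1.24.

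**Figure D3:**
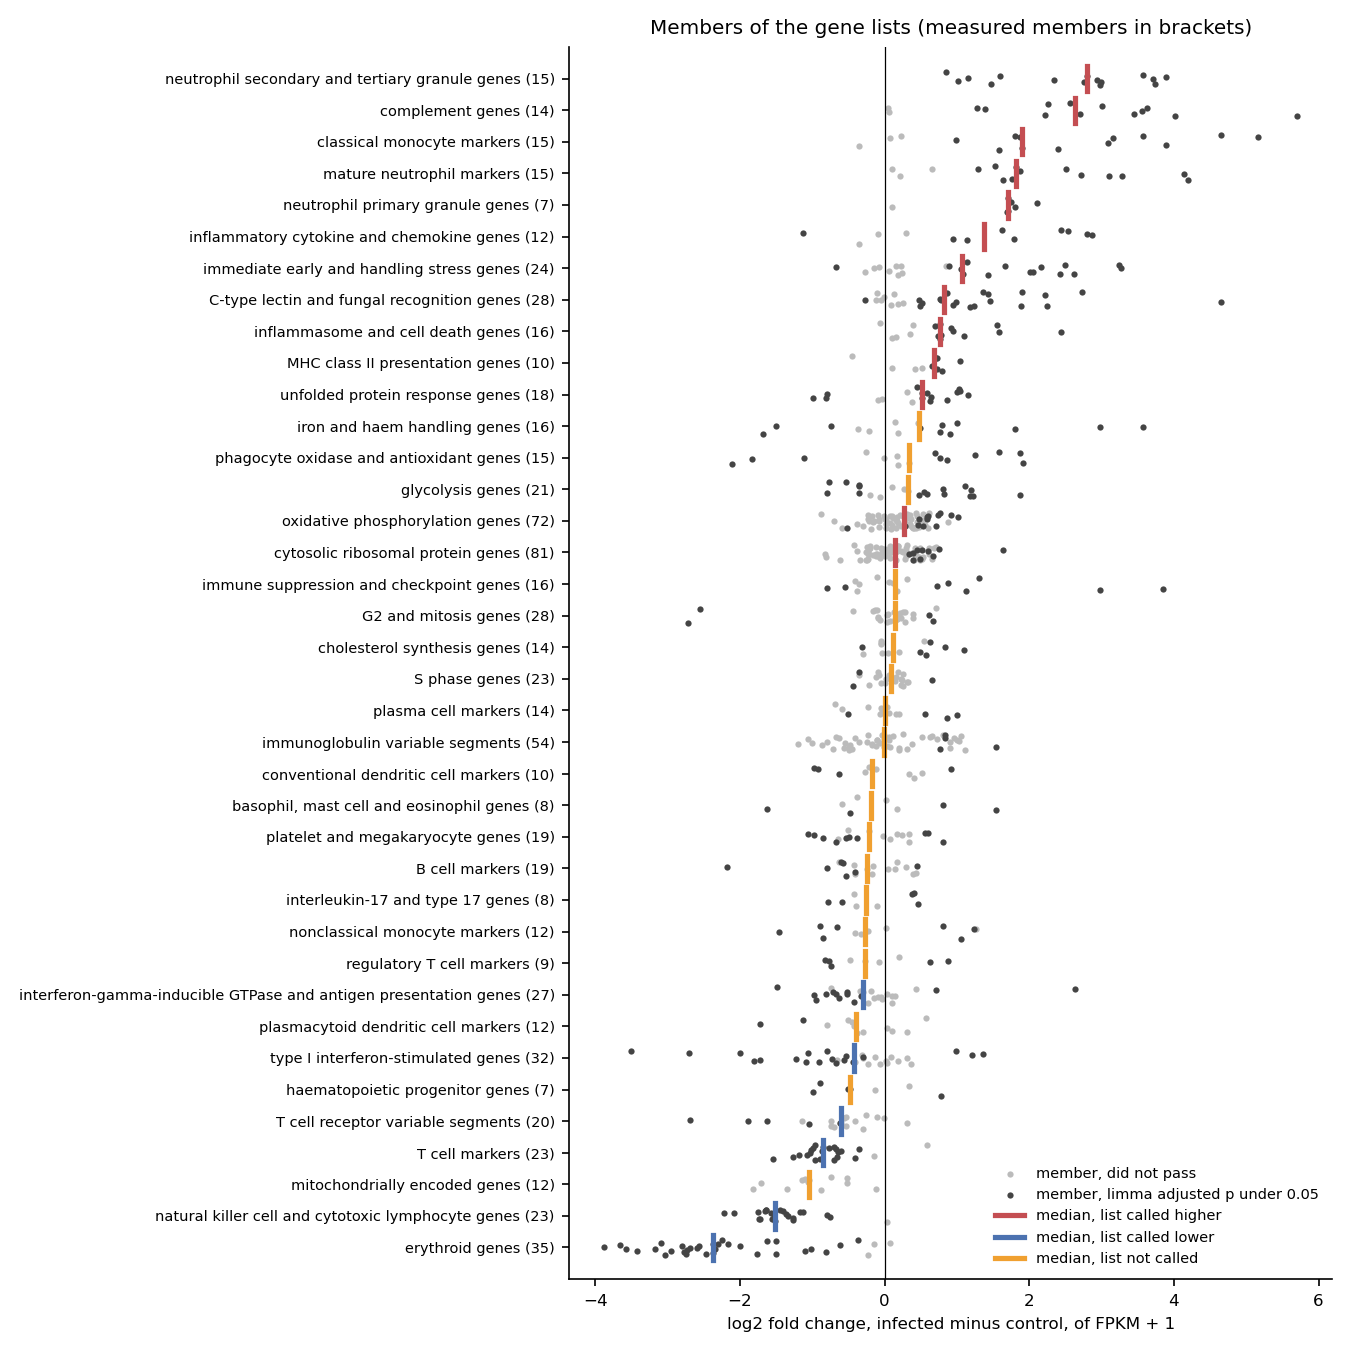
Each row is 1 of the 38 gene lists and each point a measured member, placed by its log2 fold change between infected and control libraries of FPKM + 1; dark points passed the limma test and coloured ticks are list medians. Medians run from -2.36 for erythroid genes to 2.79 for secondary and tertiary granule genes, and on TPM the medians of both interferon lists turn positive.

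Over the 38 lists, limma's camera test with a preset correlation of 0.01 called 13 higher and 6 lower. With an estimated correlation 4 calls held, those of secondary and tertiary granule genes, classical monocyte markers, erythroid genes and immediate early genes. In simulated data with 3 libraries per group, 23.3% of genes changed by 1.5-fold, 82.7% of those changed by 2-fold and 100% of those changed by 4-fold were recovered. Only 200 genes changed per simulated run, far fewer than were called here, so recovery in the data may differ.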

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

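The fits with voom on recovered reads, protein-coding genes and mitochondrially encoded mRNAs alone, and the tests on splits of the libraries were chosen after the data were seen, and the others before. Of 19 called lists, 15 kept their call and direction with camera at the preset correlation under each setting that could move them, up to 18, of filter, scaling, model and library, and 14 of these also with limma's fry. Camera's direction is relative to other genes: the median of the type I interferon list, among the 15, turned positive on TPM, at 0.34. The count of genes (3517) rose to 8322 on TPM (7864 higher, 458 lower, median gene 0.66) and 5919 with voom and library totals (5017 and 902, median gene 0.46), the shift of the median gene being part of each construction. Of the genes called on both scales, 145 were called in the opposite direction on TPM. The higher calls (1608) became 2640 and the lower calls (1909) 1253 when globin, immunoglobulin and mitochondrial genes were removed, 916 higher with a minimum of 5 FPKM, where fewer genes were tested, and 2505 higher with array weights; the cause was not tested for the last. With each library left out in turn, where fewer samples were fitted, counts ran from 2282 (without infected 2) to 3953 (without infected 1), from 863 to 1721 higher and from 1222 to 2232 lower. Changes of at least 2-fold (1081) numbered 482 with a pseudocount of 5 (218 higher, 264 lower), which shrinks folds by construction, 3438 on TPM (3222 and 216), 2179 with voom and library totals (1823 and 356), and 338 higher with a minimum of 5 FPKM. Voom on recovered reads with the implied library sizes called 3758 genes, 3336 of them among the 3517.

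Called lists numbered 19 with the preset correlation and 4 with an estimated one. Fry called 24 lists: 17 of the 19 in the same direction, without oxidative phosphorylation (limma fry adjusted p = 0.097) and ribosomal protein genes (0.1795), and 7 others, 5 higher (oxidase and antioxidant, suppression, glycolysis, cholesterol and iron genes) and 2 lower (platelet and progenitor genes). The median of immunoglobulin variable segments turned to 0.49 on TPM and 0.50 with voom and library totals. Log2 fold changes that turned positive on TPM were those of Pax5 (0.0698), Myb (0.0152), Syk (0.51), Cox5a (0.27), Mcm2 (0.23), Uhrf1 (0.36) and Hsph1 (0.0555). With voom and library totals Syk (0.19) and Uhrf1 (0.0602) did so. Of 134 named genes that passed, 104 kept their call in each leave-one-out fit that tested them, and 30 lost it at least once. Some of the 104, such as Saa3, Mmp8, Vpreb3 and Cxcl2, fell under the filter elsewhere and were tested in only 3 of 6 fits. As a percent of the FPKM outside globin, immunoglobulin and mitochondrial genes, the difference between infected and control was -52.7 points for globin, 0.696 for platelet, 0.0595 for immunoglobulin and -9.27 for mitochondrial genes, against -25.3, 3.16, 0.128 and -2.80 points of all FPKM. The mitochondrial difference was 0.272 points for mRNAs alone and ran from -5.89 to 0.118 with each library left out, the latter without infected 2, whose mitochondrial rRNA was low.

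The labels do not say whether equal replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.0512, -0.0290 and -0.0563, against -0.00544 to 0.0548 for the other pairs. Deviations within a group of 3 sum to 0 for each gene, so these correlations cannot show whether samples were paired. With the replicate number as a block 2881 genes were called, 1337 higher and 1544 lower. Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 3517 genes, 1081 at 2-fold, and 19 lists, and 1 of the 10 splits reached each of these. The highest other split called 0 genes with limma (435 at an unadjusted p under 0.05), 0 at 2-fold and 16 lists, and the lowest 7 lists. Depth of 14635332 to 17474587 reads limits low genes. In simulated data 1.5-fold changes were recovered in 23.3% of cases, with 200 changed genes per run against 3517 called here, so recovery in the data may differ. The count-based fits planned for a table of raw counts were not run, as the table holds FPKM.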

Other observations

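Tests of added cell type lists, of differences between lists and of mitochondrial and ribosomal RNA in infected 2 were chosen only after the results were seen, as were the genes named here. Several genes known from resident macrophages of the peritoneal cavity appeared in all 3 infected libraries and were nearly missing from the controls. Alox15, Fn1 and Prg4, which such cells also express, were among the largest rises. Gata6, the transcription factor of these cells, had 0.0324 ± 0.0213 FPKM in control and 2.84 ± 0.08803 in infected libraries (mean ± SD, n = 3 per group). The same held for Tgfb2 at 0.0981 ± 0.0673 and 3.27 ± 0.285, Garnl3 at 0.136 ± 0.0608 and 2.92 ± 0.568, and Vsig4 at 0.0524 ± 0.0524 and 5.96 ± 1.37. Of 18 such genes with at least 10 mean reads in a group, in a list written when most of their values had been seen, 12 were at least 2-fold higher with no overlap between groups. This rule was met by 10.4% of all 14389 genes with as many reads, and by 24.7% of the 4057 genes under 1 FPKM in control with at least 10 mean reads in infected libraries, the class of 10 of the 12. No overlap in either direction and at any fold, a looser rule, has a chance rate of 10% and held for 47.0% of tested genes. The other 6 of the 18 were Ltbp1, Selp, Nt5e, Thbs1, F5 and Itga6. Thbs1 had 807 ± 37.3 FPKM in control and 729.5 ± 61.3 in infected libraries, F5 360 ± 16.5 and 372 ± 87.5, and Itga6 462 ± 14.7 and 283 ± 5.61. Nt5e, which is not abundant in controls, had 2.98 ± 0.114 and 5.14 ± 0.254. Selp is also in the platelet list. Why these 6 genes did not meet the rule was not tested.

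Of 6 Kupffer cell genes with enough reads 2 were higher by the rule of a 2-fold rise without overlap, Clec4f and Cd163, and 1 was lower, Kcna2. Of 3 alveolar and 6 red pulp macrophage genes 0 were higher. Of 3 peritoneal mast cell genes with enough reads 0 were higher and 1, Cma1, was lower, and of 8 mesothelial genes 1 had enough reads, Krt8, which was higher. Of 5 heat shock genes, the members of the handling list that respond to protein damage, 0 were higher by this rule. In infected 2 alone Alb, the liver's albumin gene, reached 33.4 FPKM, against at most 0.0996 in the other libraries. Apoa1 there had 2.49 FPKM against at most 0.188 elsewhere, and Rn7sk, a noncoding RNA, 30.4 against at most 4.11. Whether these values share a cause with the low mitochondrial rRNA of infected 2 was not tested.

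For the rise of macrophage genes, a loss of erythroid RNA would raise genes of all other cell types alike. Complement genes instead lay 2.87 above B cell markers in median log2 fold change. Relative to each gene's control mean, the difference was 2.82 to 2.99 in the infected libraries and -0.01 to 0.01 in controls, which lie around 0 by construction. This test replaced a first one, of the B cell median alone (-0.24), which turned positive on TPM. The difference restates list medians already seen and covers complement genes, not macrophage genes as such. It argues only against an equal rise of all other cell types as the whole account. Cells of the resident peritoneal macrophage type in the infected samples are a candidate source only as a hypothesis that these values cannot test: the list was written when most of its values had been seen, so the share of its genes under 1 FPKM in controls, and with at least 10 mean reads in infected libraries, that were at least 2-fold higher without overlap (10 of 10, or 100%) is no evidence for it. The other 8 of its 18 genes were at 1 FPKM or more in controls, and Ficoll does not remove macrophages. Whether other peritoneal cells came along at collection stays open, with 1 of 4 mesothelial and mast cell genes higher and too few reads for the rest. Infection is a biological alternative that the design cannot separate from collection, since the labels give different days for the groups.

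Natural killer and T cell genes fell while B cell markers were not called. One dilution of all lymphocytes would shift both alike, but the natural killer list lay below the B cell list by a median log2 difference of -1.27 and the T cell list by -0.61. Relative to the control mean, the first difference was -1.35 to -1.10 in the infected libraries and -0.07 to 0.09 in controls, and the second -0.75 to -0.39 and -0.05 to 0.04. These differences restate the pattern, so they argue only against an equal shift of all lymphocytes as the whole account. A dilution together with B cells gained from another source was not tested. A change in lymphocyte composition with infection stays open and was not tested.

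Infected 2 held little mitochondrial rRNA: mt-Rnr2 had 588 FPKM there and 13449 to 29721 in the other libraries, and mt-Rnr1 187 against 8624 to 25264. An equal loss of all mitochondrial RNA in infected 2 is argued against as the whole cause, since mt-Rnr2 stood at 0.0215 and mt-Rnr1 at 0.00817 of its control mean there, while 12 mitochondrially encoded mRNAs had a median of 0.456 and a lowest value of 0.0950, that of mt-Nd4l, which is 4.41 times the higher rRNA value (3.63 times when set against the other infected libraries). Less mitochondrial RNA of every kind in infected 2 stays open as part of the cause and depends on the scaling: 11 of the 12 mRNAs lay below each control there in FPKM, such as mt-Nd4 at 157 against 537 to 790, but 8 did as shares of reads and 6 as shares of summed FPKM, of which all mitochondrial mRNAs took 1.12% against 1.10% to 1.27% in controls, and in a first test 11 of the 12 were above infected 3, whose mRNAs were low too. Less ribosomal RNA of every kind, as a more complete removal of rRNA would give, may be the cause but rests on 1 nuclear rRNA gene with at least 100 mean reads, CT010467.1, lowest in infected 2 at 20.9 FPKM against 149 to 319 elsewhere, and this test replaced a first version with 9 nuclear rRNA genes at any read number that passed the filter (2 lowest in infected 2) after its result was seen, since 8 of the 9 lie near the floor. No biological explanation was tested, since the labels set infected 2 apart in nothing.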
